A study of Homo sapiens with 8 samples.

How the data were processed

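The measurements were mRNA levels in SK-MEL-5 melanoma cells on 8 Affymetrix arrays in 4 groups of 2: DMSO, THZ1, siCtrl and siMITF. Per the labels' protocols, THZ1 was given at 250 nM for 6 h, 100 ng of RNA was used per array, and ERCC spike-in RNA was added in proportion to cell number. The labels give neither the duration of the DMSO treatment nor the time of harvest after siRNA. Per the submitters' processing notes, probe sets were summarised with MAS5, with no version given. The deposited values are array signals (intensity) on a linear scale, normalized to cell number per the series' design text. How that normalization was calculated is not recorded. The ERCC signals were about equal within the drug arrays and within the siRNA arrays, but lower in the second set (median 256 and 257 with siCtrl, 529 and 534 with DMSO), so the sets look scaled separately. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples.

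Of 49495 probe sets, 45284 carried 1 gene symbol, 1333 several and 2682 none, and 100 were ERCC and 102 other control probe sets. Gene IDs of 45214 probe sets matched a reference gene table (GRCh38.p14), and 70 kept the platform's symbol. Signals were analysed as log2(value + 16). A gene was represented by its brightest probe set with 1 symbol. It was tested if the mean log2 signal of that probe set was at or above a cut, a signal of 39.2. The cut was the 40th percentile of all probe sets with 1 symbol, and it left 11946 of 18244 genes. Of the tested probe sets, 1585 had names ending in _x_at and 2260 in _s_at, designs that can detect related sequences.

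Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 arrays, empirical Bayes variances and a Benjamini-Hochberg adjusted p under 0.05. Tests of at least 2-fold also required an absolute log2 change of 1 or more. The comparisons were THZ1 with DMSO, siMITF with siCtrl, the difference of these changes, and siCtrl with DMSO. Array offsets, each the median deviation of an array's tested genes from their mean over all arrays, were compared by an exact two-sided permutation test. The prior degrees of freedom were infinite per cell, so each gene had the same SE of 0.25, and the prior was 5.97 beside 4 residual degrees of freedom on the relative scale. Arrays of a group differed by an offset shared by most genes, so per-cell tests of different genes are not independent. The per-cell SE includes this offset, as the median SE on the relative scale was 0.084. The infinite prior treats the per-cell SE as exactly known, so small per-cell p values overstate the evidence. The relative scale centres each array on the median deviation of its tested genes from their mean over all arrays. The median gene then lies near 0 but not at it, with a change of 0.037 with THZ1 and 0.0014 with siMITF. This scale was chosen after seeing the data. It replaced an earlier centring on the median of tested genes that had also been tried after seeing the data. Tests with each gene's own variance were also added after the results were seen.

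Before the data were examined, 25 gene lists with 624 genes were written from general knowledge, of which 580 genes had a probe set and 524 were tested. They cover pigmentation, reported MITF targets, lineage transcription factors, the invasive state, immediate early and MAPK output genes, CDK7 and RNA polymerase II, G1/S, G2/M, homologous recombination and Fanconi, p53, apoptosis, integrated stress, heat shock, histones, interferon, NF-kB, lysosome, oxidative phosphorylation, ribosomal proteins, glycolysis and cholesterol. Markers of keratinocytes, fibroblasts and leukocytes complete them. The 24 lists with at least 5 tested genes were tested with camera, which compares a list with the other genes. It was run at a preset correlation of 0.01 and again with an estimated correlation. Per cell the estimates were 0.77 to 0.97, because the array offset is shared by most genes, so that version could hardly call any list. On the relative scale they were -0.05 to 0.32, but 0.715 for ribosomal proteins. On that scale the pigmentation list with siMITF had an estimate of 0.00116, below the preset. Its camera adjusted p was still 1.65e-04 with the preset and 0.140 with the estimate. A call lost with the estimated version is therefore not evidence of correlation within a list. The lists were also tested with fry, which asks whether a list moved at all, or on the relative scale whether it moved relative to the median gene. Named genes followed a rule fixed before the data were examined: MITF and CDK7; the 8 largest passing falls and 8 largest rises per comparison with both treated arrays outside the control range; up to 4 members per list with the lowest adjusted p; and the 5 largest differences in each direction. Loci whose symbols begin with LOC or are only clone names were skipped. TYR, TBX2 and DDIT4 after siMITF, and the genes so marked in the closing section, were chosen after their values were seen. DCN, LUM, POLR2A, HSPA1A and the other non-passing genes named are list members under the rule.

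In a single simulated draw for each comparison, 200 of 11946 genes were changed, 50 per size. For THZ1, the per-cell test recovered 2 at log2 0.5, 48 at 1, 50 at 1.5 and 50 at 2, with 0 false calls, and the relative test 48, 50, 50 and 50 with 11 false calls. For siMITF the per-cell test recovered 4, 48, 50 and 50 with 0 false calls, and the relative test 46, 50, 50 and 50 with 13. A single draw gives no rate of false calls. Over 100 draws with no change but array offsets, per-cell calls had a median of 0 in each comparison. Their maximum was 11685 for THZ1 and 11881 for siMITF. Alternatives tried were pseudocounts of 1 and 64, no filter and a 60th percentile filter, quantile normalization, centring on gene probe sets or on ERCC, the mean of a gene's probe sets, each probe set tested alone, 4 arrays per fit, a trended and robust prior, a replicate block, and omission of each array. Probe sets with several or no symbols were tested apart from the genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.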

Results

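Gene expression was measured in SK-MEL-5, an established human melanoma cell line, on 8 Affymetrix arrays in 4 groups of 2. One pair of groups compared THZ1, a covalent inhibitor of the cyclin-dependent kinase CDK7, given at 250 nM for 6 h, with DMSO, its solvent. The other compared an siRNA against MITF, the transcription factor that directs the melanocyte lineage (siMITF), with a control siRNA (siCtrl). By the series' title, the study asks whether inhibition of CDK7 depletes lineage genes in melanoma. By the series' design text the deposited signals were normalized to cell number, and ERCC spike-in RNA was added in proportion to cell number. How the normalization was calculated is not recorded, so changes called per cell are changes on the deposited scale. The median signal over 49495 probe sets was 61.3 and 76.1 on the DMSO arrays and 51.1 and 67.6 on the THZ1 arrays. It was 51.1 and 59.3 with siCtrl, and 40.1 and 32.5 with siMITF. Arrays of one group correlated at r = 0.994 to 0.995 over gene probe sets, but differed by an offset shared by most genes. Changes are therefore given per cell and also relative to the median gene, after each array was centred, a scale chosen after seeing the data. The number of arrays limits the precision. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays.

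MITF mRNA was lower on both siMITF arrays than on both siCtrl arrays. Its signal was 1747 and 1168 with siMITF against 3436 and 3936 with siCtrl, a log2 change of -1.35 (SE 0.25, n = 2 per group), or 2.56-fold lower per cell (limma, adjusted p = 1.62e-06). MITF also fell 1.65-fold relative to the median gene (log2 change -0.72, SE 0.10, adjusted p = 3.25e-04). A second MITF probe set gave -1.37 per cell and -0.74 relative. With THZ1 the MITF signal was 3311 and 4178 against 4670 and 5669 with DMSO, a log2 change of -0.47 (SE 0.25) that did not pass the test (adjusted p = 0.280). This change was -0.27 relative to the median gene (SE 0.10, adjusted p = 0.0498), and the second probe set gave -0.31. The THZ1 and siMITF changes of MITF differed by 0.89 per cell (SE 0.35, adjusted p = 0.0706) and by 0.45 relative to the median gene (adjusted p = 0.0218).

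**Figure D1:**
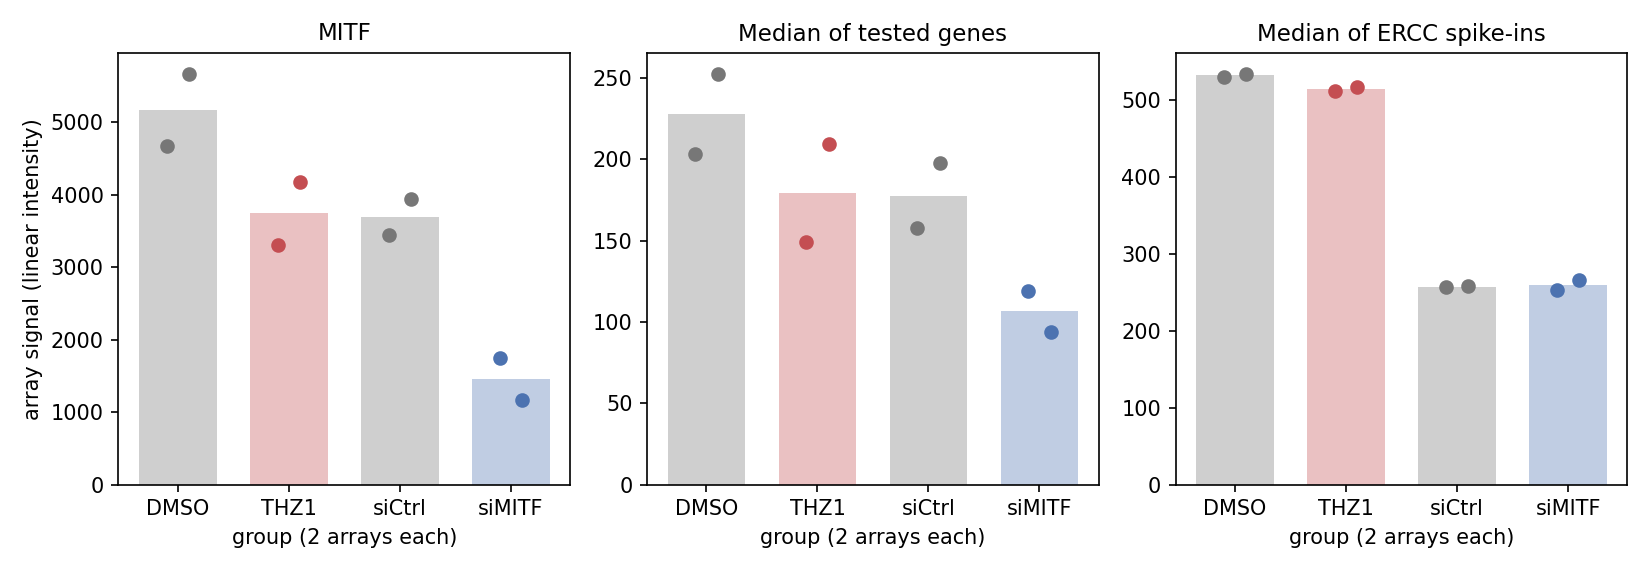
Array signal (linear intensity, y axes from 0) of MITF, of the median tested gene and of the median ERCC spike-in in the 4 groups (x axis); points are the 2 arrays of a group and bars their mean. MITF was at 1747 and 1168 with siMITF against 3436 and 3936 with siCtrl, while the spike-ins of both groups lay between 253 and 266.

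With THZ1, 1199 genes were lower and 9 higher per cell, against 2520 lower and 2112 higher relative to the median gene. The largest falls were those of ZC3H4, a zinc finger protein that restrains noncoding transcription (log2 change -2.48, 5.59-fold lower), CYREN, a regulator of DNA end joining (-2.11), PLEKHA5 (-2.04) and the cell cycle transcription factor E2F5 (-2.02). ZNF518B (-1.95), CASP8AP2 (-1.94), INTS6, a subunit of the Integrator complex that acts on RNA polymerase II (-1.93), and MOCS3 (-1.93) followed. The 8 largest rises were smaller: LSMEM1 (1.21, 2.32-fold higher), SNAPC3, a subunit of the snRNA-activating complex (1.14), ID2, an inhibitor of basic helix-loop-helix factors (0.92), HSP90B2P (0.87), the immediate early gene IER2 (0.85), KLF10 (0.79), the bromodomain protein BRD2 (0.78) and CSMD1 (0.77). Each of these 16 genes passed the test (n = 2 per group, SE 0.25) with both THZ1 arrays outside the range of the DMSO arrays. Their limma adjusted p values ran from 5.71e-20 for ZC3H4 to 0.0221 for CSMD1. These overstate the evidence, since the SE shared by all genes is treated as exactly known. With each gene's own variance the lowest per-cell adjusted p was 0.268. HSP90B2P is a pseudogene close in sequence to HSP90B1, so its signal is uncertain. Other probe sets of some of these genes disagreed: relative to the median gene, ZC3H4 had -2.28 on the tested probe set and -0.24 on another, SNAPC3 1.33 against 0.20 to 0.26 on 3 others, and CSMD1 0.97 against -0.10. CDK7 itself, a target of THZ1, had a log2 change of -0.60 (SE 0.25, adjusted p = 0.105), and -0.41 relative to the median gene (adjusted p = 0.00148).

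Some transcription factors of the melanocyte lineage fell with THZ1. Of 17 tested members, 7 were lower and 0 higher per cell (8 lower adjusted over the list alone), and 9 were lower relative to the median gene. SNAI2, a neural crest factor, fell by 1.60 on the log2 scale (adjusted p = 2.51e-08), TBX2 by 1.42, SOX10, which activates MITF, by 1.36 (adjusted p = 3.94e-06) and LEF1, a Wnt effector, by 0.87. SOX10 had -1.16 on the tested probe set and -0.25 on another, both relative to the median gene. The list passed camera (adjusted p = 3.96e-05), but not with an estimated correlation (adjusted p = 0.969 per cell, 0.146 relative to the median gene). Of 23 genes of pigmentation and the melanosome 0 passed the test per cell, 3 were lower and 6 higher relative to the median gene, and camera gave an adjusted p of 0.380. MC1R, the melanocortin receptor, had -0.64 per cell (adjusted p = 0.0761) and -0.44 relative to the median gene (adjusted p = 0.00263). MLPH, melanophilin, had -0.56 (adjusted p = 0.148) and -0.36 (adjusted p = 0.00870). Among 37 reported MITF targets outside pigmentation, 8 were lower and 0 higher (8 adjusted over the list alone), including MBP (-1.69) and the mitochondrial coactivator PPARGC1A (-1.15), as well as SNAI2 and TBX2, and 9 were lower and 7 higher relative to the median gene. That list did not pass camera (adjusted p = 0.345).

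Some DNA replication and repair genes also fell with THZ1. Of 28 G1/S and replication genes, 7 were lower and 0 higher (12 lower adjusted over the list alone), with GINS1 (-1.25), the licensing factor CDT1 (-1.16), E2F3 (-0.96) and MCM10 (-0.93). Of 25 homologous recombination and Fanconi genes, 7 were lower and 0 higher (12 over the list alone), with PALB2 (-1.44), the helicase BLM (-1.38), FANCF (-1.07) and BARD1 (2.01-fold lower). On the relative scale 17 of the former and 14 of the latter were lower and 0 higher. Both lists passed camera (adjusted p = 2.32e-04 and 3.96e-05). With an estimated correlation they did not: adjusted p = 0.969 for both per cell, and 0.440 and 0.220 relative to the median gene. Of 30 G2/M genes 4 were lower (6 over the list alone), among them the centromeric histone CENPA (-1.76) and AURKB (-0.83), and 12 were lower and 1 higher relative to the median gene. Its camera adjusted p was 0.0586 per cell and 0.0199 relative to the median gene, or 0.576 on that scale with an estimated correlation.

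The mRNAs of respiration and of ribosomal proteins lay above the median gene with THZ1. Relative to it, 28 of 30 oxidative phosphorylation genes were higher (COX6C 0.51, NDUFA1 0.48), 32 of 41 cytosolic ribosomal protein genes (RPL7 0.47, RPS9 0.43) and 22 of 36 lysosome and autophagy genes (MAP1LC3B 0.64). Per cell 0 members of these 3 lists passed in either direction, and the list medians were 0.12, 0.08 and 0.05. The 3 lists passed camera (adjusted p = 2.36e-06, 2.36e-06 and 2.32e-04). With an estimated correlation the adjusted p was 0.969 for each per cell, and 0.0498, 0.551 and 0.220 relative to the median gene. Random lists of the same signal also lay high, with a median of 0.27 for the ribosomal protein list, whose own median was 0.28. Quantile normalization gave that list a camera adjusted p of 0.366.

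Smaller groups moved with THZ1 in part. Of 13 anti-apoptotic genes 3 fell: BCL2L2 (-1.05), XIAP (-0.94) and the caspase-8 inhibitor CFLAR (-0.85). Of 25 integrated stress and unfolded protein response genes 5 fell, led by XBP1 (-1.27) and CEBPB (-1.07). Of 27 immediate early genes 2 fell, KLF2 (-0.91) and ZFP36 (-0.77), and 2 rose, IER2 and KLF10. Of 19 MAPK output genes 2 fell, SPRED1 (-1.06) and PHLDA1 (-0.90), and of 24 p53 targets 2, of which XPC had -0.96. Of 35 genes of the CDK7 complex and the RNA polymerase II machinery 1 fell, the TFIIH subunit GTF2H1 (-1.05), while POLR2A had 0.58 (adjusted p = 0.129). Among 16 heat shock genes DNAJB1 fell (-0.79) and HSPA1A had 0.33 (adjusted p = 0.568). On the relative scale 9 heat shock genes were higher and 1 lower, and of the CDK7 and polymerase II list 11 were higher and 5 lower. One gene fell in each of the NF-kB list (IL6, -0.98, of 16), the interferon list (IRF9, adjusted p = 0.00139, of 24), the cholesterol list (INSIG1, -0.98, of 18) and the invasive state list (POU3F2, -0.70, of 14). Adjusted over the list alone, 0 invasive state genes passed, 3 MAPK output genes, 4 p53 targets and 8 stress genes, and the other counts stayed as they were. Lower and higher counts on the relative scale were 3 and 1 for anti-apoptotic, 9 and 3 for stress, 9 and 6 for immediate early, 8 and 4 for MAPK output and 7 and 6 for p53 genes. They were 3 and 1 for NF-kB, 6 and 2 for interferon, 3 and 6 for cholesterol and 2 and 3 for invasive state genes. Of the lists in this paragraph so far, only the heat shock list passed camera (upward, adjusted p = 0.0441), with adjusted p from 0.326 to 0.858 for the others. The glycolysis list also passed upward (adjusted p = 0.0325) with 0 of 19 members passing per cell, and 2 lower and 8 higher relative to the median gene. Both had an adjusted p of 0.969 with an estimated correlation. Without the filter the heat shock genes had an adjusted p of 0.0994 and the glycolysis genes 0.0618, and with quantile normalization both had 0.366. With the mean of probe sets the heat shock genes had 0.0970. Of 12 histone genes 0 passed per cell, and 1 was lower and 3 higher relative to the median gene. Some genes had other probe sets of opposite sign relative to the median gene: KLF2 1 of 1, IL6 1 of 1, PHLDA1 2 of 3 and INSIG1 1 of 2. For MLPH it was 2 of 5, for XIAP 1 of 3 and for INTS6 1 of 6. Of the markers of other cell types, 0 of 5 fibroblast genes, 0 of 6 leukocyte genes and 0 of 3 keratinocyte genes passed per cell. On the relative scale 4 of the 5 fibroblast genes were higher, among them DCN (0.51) and LUM (0.42).

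In total 1199 of 11946 genes were lower and 9 higher per cell with THZ1 (adjusted p under 0.05), of which 391 and 2 changed at least 2-fold. Relative to the median gene the counts were 2520 lower and 2112 higher, and 187 and 5 at least 2-fold. On that scale 1192 of the 1199 genes were also lower, and the median gene itself had 0.037, which favours calls of higher. The median gene changed by -0.16 on the log2 scale, but by 0.04 without THZ1 replicate 1, -0.0139 without DMSO replicate 2, -0.32 without DMSO replicate 1 and -0.37 without THZ1 replicate 2. Of 100 simulated draws with no change, 56 gave as large a shift. The array offsets (median deviations of tested genes from their means over all arrays) differed by -0.20, with 3 of 4 array pairs below 0. Their exact two-sided permutation p was 0.667, where 0.333 is the smallest this design allows. No list passed fry per cell (0 of 24, adjusted p from 0.745 to 0.945), while 17 did relative to the median gene. As limits, with each gene's own variance 0 genes passed per cell (lowest adjusted p 0.268, 1444 genes at an unadjusted p under 0.05) and 3230 relative to the median gene. Of 100 simulated draws with no change but array offsets of SD 0.22, 4 gave at least 1208 calls. The per-cell count was 2102 without THZ1 replicate 2, 368 without THZ1 replicate 1 and 250 without DMSO replicate 2. At least 2-fold, 673 changed without DMSO replicate 1, 250 without DMSO replicate 2, 216 without THZ1 replicate 1 and 830 without THZ1 replicate 2.

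With siMITF, most pigmentation genes and reported MITF targets were lower than with siCtrl. Of 23 pigmentation and melanosome genes, 21 were lower and 0 higher per cell (22 over the list alone), and 14 were lower and 1 higher, TYR (0.36), relative to the median gene. RAB32 and RAB27A, small GTPases of melanosome biogenesis and transport, had log2 changes of -1.85 and -1.76, and SLC45A2, a melanosomal transporter, and GPR143 had -1.72 and -1.53. Their relative changes were -1.21, -1.13, -1.08 and -0.90. A second TYR probe set had a relative change of -0.00. Of 37 reported MITF targets outside pigmentation, 33 were lower and 0 higher (35 adjusted over the list alone), and 24 were lower and 1 higher, TBX2 (0.44), relative to the median gene. MBP (-1.68), PPARGC1A (-1.63), the ceramidase ASAH1 (-1.60) and SEMA6A (-1.57) had the lowest adjusted p. Both lists passed camera (adjusted p = 3.81e-06 and 9.47e-08). With an estimated correlation the adjusted p was 0.977 for both per cell and 0.140 for both relative to the median gene.

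Genes of cell division fell further than the median gene with siMITF. Of 30 G2/M and mitosis genes, 30 were lower on both scales, with a median relative change of -0.72. MAD2L1 of the spindle checkpoint (log2 change per cell -1.63), BIRC5 (-1.61) and the kinesins KIF23 (-1.58) and KIF2C (-1.56) were among them. Of 28 G1/S and replication genes, 28 were lower per cell and 27 relative to the median gene, with CDC45 (-1.64), cyclin A gene CCNA2 (-1.59), MCM5 (-1.57) and TK1 (-1.53). The adjusted p of camera was 6.59e-21 and 2.06e-17. With an estimated correlation it was 0.977 for both per cell and 0.140 for both relative to the median gene. Per cell the adjusted p of fry, which there tests a list without comparing it with other genes, was 0.0697 for both. Relative to the median gene it was 1.84e-04 for both, but the centring of that scale already sets a list against the other genes.

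**Figure D2:**
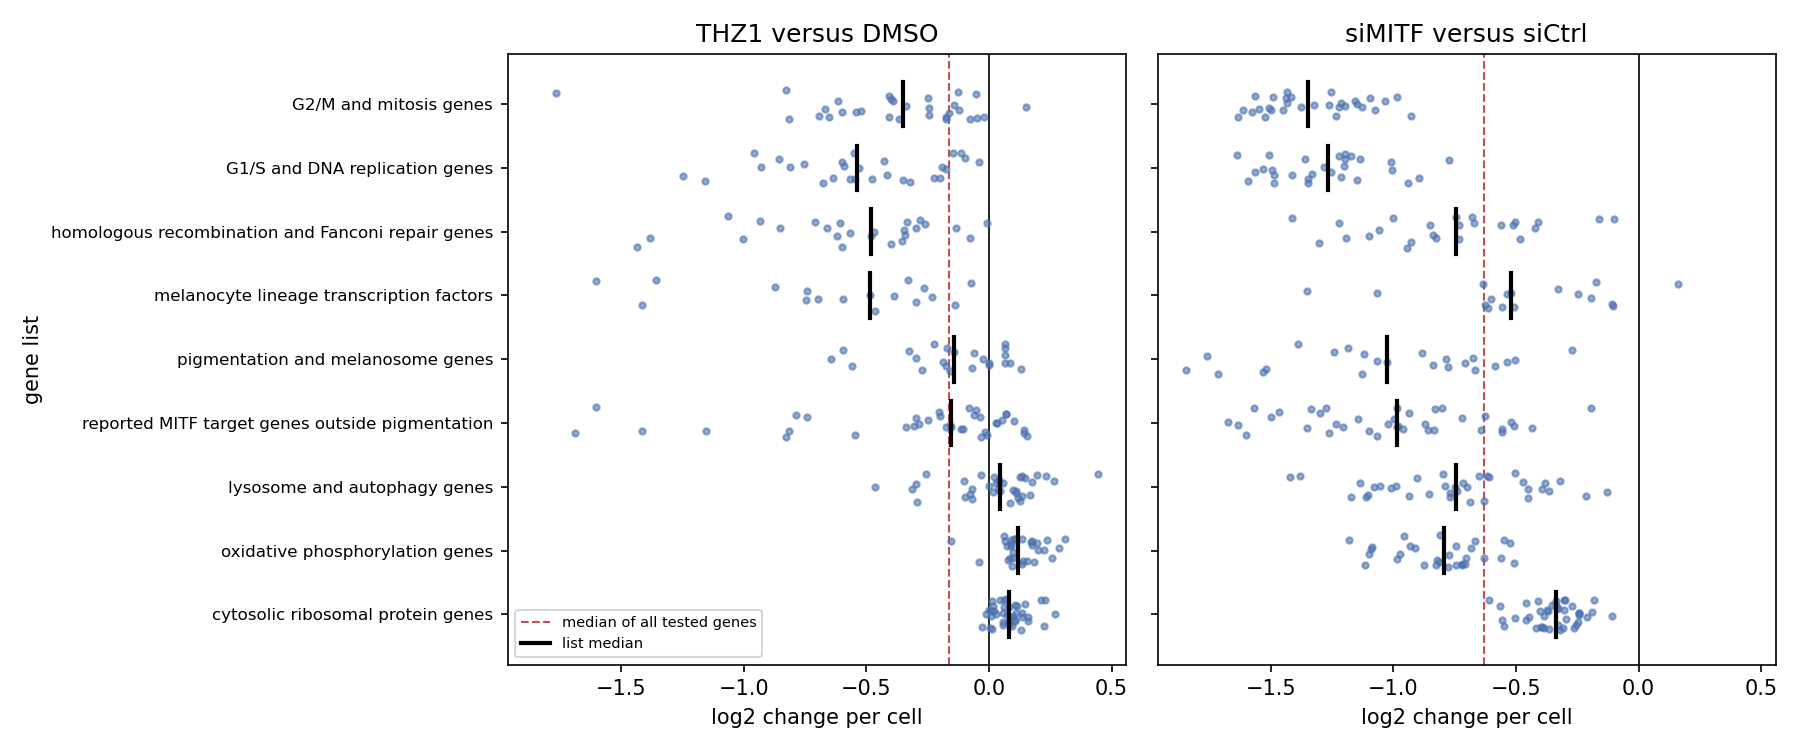
Log2 change per cell (x axis) of each tested gene (points) in 9 gene lists (y axis) for THZ1 versus DMSO and siMITF versus siCtrl; black bars are list medians, the dashed line is the median of all tested genes (-0.16 and -0.63), and vertical jitter has no meaning. With siMITF the G2/M, G1/S and pigmentation medians lay at -1.35, -1.27 and -1.02, left of the dashed line, and the ribosomal protein median at -0.34, right of it.

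Among all genes, the largest falls with siMITF were those of the transporter ABCB5 (log2 change -2.19, 4.57-fold lower), the hyaluronan synthase HAS2 (-2.01), TRIM63 (-1.93), the splicing factor ESRP1 (-1.90), FAM83D (-1.89), APOLD1 (-1.89), DYNC1I1 (-1.88) and RAB32. The largest rises were those of the matrix protein MATN2 (1.81, 3.50-fold higher), the protease inhibitor SERPINA3 (1.49), chromogranin B gene CHGB (1.45), the receptor phosphatase PTPRZ1 (1.33), the histone gene H2BC5 (1.19), the mTOR inhibitor DEPTOR (1.17), ABCA8 (1.12) and CEBPD (1.07). Each passed the test on both scales (n = 2 per group, per-cell SE 0.25), with per-cell limma adjusted p values from 4.77e-15 for ABCB5 to 1.30e-04 for CEBPD. These too overstate the evidence. With each gene's own variance the lowest per-cell adjusted p was 0.0893. Of 4 other TRIM63 probe sets 2 had the opposite sign relative to the median gene. CDK7 had -0.61 per cell (adjusted p = 0.0251) and 0.03 relative to the median gene (adjusted p = 0.784).

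Most ribosomal protein mRNAs lay above the median gene with siMITF. Of 41 tested, 4 were lower per cell (0 adjusted over the list alone), including RPL4 (-0.61) and RPL7 (-0.57), and 30 were higher relative to the median gene, where RPL4 and RPL7 had 0.02 and 0.07. The list passed camera upward (adjusted p = 1.36e-05; 0.977 with an estimated correlation, 0.531 so estimated on the relative scale). Histone genes also passed upward (adjusted p = 0.00445, 0.977 with an estimated correlation) and split: H2BC5 rose, while H2AX fell by 1.33 per cell. On the relative scale 6 of 12 were higher and 4 lower, and camera gave an adjusted p of 0.158. The p53 target list passed narrowly upward (adjusted p = 0.0495, 0.977 with an estimated correlation), although 10 of its 24 genes were lower per cell, including TIGAR (-0.95), and 9 over the list alone. Oxidative phosphorylation genes passed downward (adjusted p = 0.0484, 0.977 with an estimated correlation, 0.140 so estimated on the relative scale); 28 of 30 were lower per cell (30 over the list alone) and 11 relative to the median gene, with SDHD (-1.18) and UQCRC1 (-1.09). These 4 list calls depended on the processing. The adjusted p for oxidative phosphorylation genes was 0.253 with pseudocount 1, 0.324 with the 60th percentile filter, 0.353 with quantile normalization, 0.0848 centred on the median of gene probe sets and 0.0743 centred on ERCC spike-ins. For p53 target genes it was 0.151 with pseudocount 64, 0.837 with no filter and 0.195 with the mean of probe sets. For histone genes it was 0.0757 with pseudocount 64 and 0.246 with quantile normalization. For cytosolic ribosomal protein genes it was 0.118 with no filter and 0.0565 with the trended and robust variance prior.

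The other 16 tested lists did not pass camera with siMITF, with adjusted p from 0.0722 to 0.898. Of 17 lineage transcription factors 8 were lower per cell, MITF and IRF4 (-1.07) among them, while 2 were lower and 7 higher relative to the median gene. Counts of lower genes per cell were 18 of 25 for homologous recombination and Fanconi genes (FANCI -1.41), 9 of 13 for anti-apoptotic genes (BCL2A1 -1.47), 13 of 27 for immediate early genes (FOS -1.31, EGR1 -1.03) and 11 of 19 for MAPK output genes (DUSP4 -1.05). They were 29 of 35 for the CDK7 and polymerase II list (POLR2D -1.19), 9 of 16 for heat shock genes (HSP90AA1 -0.94), 12 of 24 for interferon genes (ISG20 -1.35) and 9 of 16 for NF-kB genes (TNFAIP3 -1.33). They were 26 of 36 for lysosome and autophagy genes (ATP6V0D1 -1.42, SQSTM1 -1.14), 14 of 19 for glycolysis (PFKFB3 -1.43), 15 of 18 for cholesterol genes (IDI1 -1.52) and 6 of 14 for invasive state genes (TPM1 -1.10). Of 25 integrated stress genes 18 were lower, led by SLC7A11 (-1.46), and 1 higher, DDIT4 (0.75). On the relative scale, lower and higher counts were 9 and 2 for homologous recombination, 5 and 0 for anti-apoptotic, 7 and 8 for immediate early, 4 and 3 for MAPK output and 10 and 3 for CDK7 and polymerase II genes. They were 2 and 6 for heat shock, 5 and 7 for interferon, 3 and 5 for NF-kB, 12 and 5 for lysosome and 4 and 3 for glycolysis genes. They were 7 and 1 for cholesterol, 1 and 6 for invasive state and 7 and 6 for integrated stress genes. Adjusted over the list alone, the per-cell lower counts became 6 for lineage factors, 3 for invasive state, 12 for immediate early, 20 for homologous recombination, 6 for heat shock, 15 for glycolysis and 17 for cholesterol genes. Some genes had other probe sets of opposite sign relative to the median gene: EGR1 4 of 5, TPM1 4 of 6 and TIGAR 1 of 1. For SEMA6A it was 1 of 3, for BIRC5 1 of 10 and for ATP6V0D1 1 of 6. Of the markers of other cell types, 3 of 3 keratinocyte genes (CDH1 -0.87), 2 of 5 fibroblast genes (LUM -1.06) and 4 of 6 leukocyte genes (CD68 -0.87) were lower per cell. Relative to the median gene 0, 1 and 1 were lower and 0, 2 and 1 higher.

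In total 7568 of 11946 genes were lower and 39 higher per cell with siMITF, of which 1624 and 11 changed at least 2-fold. Relative to the median gene 2946 were lower and 2329 higher, and 42 and 79 at least 2-fold. All 2946 were also lower per cell, and the 39 higher genes were higher on both scales. The median gene changed by -0.63 on the log2 scale, or 1.55-fold. The array offsets differed by -0.63, with 4 of 4 array pairs below 0 (-0.90 to -0.37). Their exact two-sided permutation p was 0.333, the smallest this design allows. No list passed fry per cell (0 of 24, adjusted p from 0.0697 to 0.225) and 17 did relative to the median gene. As limits, with each gene's own variance 0 genes passed per cell (lowest adjusted p 0.0893, 5706 at an unadjusted p under 0.05) and 3688 relative to the median gene. Of 100 simulated draws with no change but array offsets of SD 0.22, 6 gave at least 7607 calls. The per-cell count was 1771 without siCtrl replicate 2 and 1850 without siMITF replicate 2. At least 2-fold, 3114 changed without siCtrl replicate 1, 832 without siCtrl replicate 2, 3191 without siMITF replicate 1 and 781 without siMITF replicate 2.

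The THZ1 and siMITF changes were compared gene by gene, each against its own control. KLF9 (difference of log2 changes -2.23, SE 0.35), CEBPD (-2.22), LMCD1 (-2.10), CLDN14 (-2.09) and FHDC1 (-2.02) had the most negative differences, that is, a lower change with THZ1 than with siMITF. DYNC1I1 (2.06), PHLDA2 (2.01), C11orf96 (1.95), IER2 (1.90) and ALDH9A1 (1.87) had the most positive. The difference passed for 1288 genes, 113 negative and 1175 positive, and relative to the median gene for 2409 and 2556. Per cell 765 genes fell in both comparisons, against 760 for independent lists of 1199 and 7568 genes. Relative to the median gene 745 fell in both against 621, and 604 were higher with THZ1 and lower with siMITF against 521. On that scale 525 were lower with THZ1 and higher with siMITF against 491. Per cell 0 genes rose in both, against 0.0294 for lists of 9 and 39, and relative to the median gene 440 did against 412. Every combination of directions thus exceeded independence on the relative scale, so the excess is not particular to genes falling in both. Across genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson r of 0.0357 and a Spearman rho of 0.0384. The per-cell count of differing genes was 98 without DMSO replicate 1, 82 without either siCtrl replicate 2 or siMITF replicate 2, 245 without THZ1 replicate 2 and 3923 without THZ1 replicate 1. The per-cell overlap was 144 without DMSO replicate 2, 187 without siCtrl replicate 2, 210 without siMITF replicate 2, 227 without THZ1 replicate 1 and 1536 without THZ1 replicate 2.

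Between the controls, 731 genes were lower and 16 higher with siCtrl than with DMSO on the deposited scale, and 1729 and 1311 relative to the median gene. On the latter scale, 19 of 30 G2/M genes and 10 of 28 G1/S genes were higher and 0 lower with siCtrl, and 12 of 36 lysosome genes were lower and 0 higher (camera adjusted p = 1.13e-09, 0.00160 and 0.00160; 0.747 for each with an estimated correlation). The median ERCC signal was 256 and 257 with siCtrl against 529 and 534 with DMSO, so the sets appear to have been scaled separately and levels should not be set across them per cell. Centring on the spike-ins turned the counts to 72 lower and 8397 higher. On the deposited scale 138 genes passed without DMSO replicate 2, 133 without siCtrl replicate 1, 458 without siCtrl replicate 2 and 1345 without either THZ1 array.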

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

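The weighing of the lower median gene used tests chosen only after that result was seen; the matched-list tests were written before their values were seen. Samples far from the others were not tested for in groups of 2 arrays. Signals in data outside the comparisons, probe sets assigned to no single gene, gave these results. Of 753 tested probe sets with several gene symbols, 1 was higher with THZ1 than with DMSO (log2 change 1.21, adjusted p = 9.23e-05) and 31 were lower. Of 1393 tested probe sets with no gene symbol, 3 were higher with siMITF than with siCtrl (log2 changes 0.56, 0.71 and 0.64, adjusted p = 0.0343, 0.00846 and 0.0162) and 917 were lower. The cause was not tested.

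The median gene was lower per cell with siMITF. The fall was not confined to the ends of the signal range, where background or saturation would act. The 4187 genes of middle signal (mean log2 of 8 to 11) had a median log2 change of -0.85. Falls were smaller at the ends, with medians of -0.40 at a mean log2 of 5 to 6 and -0.48 at 12 to 15. How far background or saturation changed the size of the shift was not tested. Unequal cell counting, RNA recovery or spike-in addition was left open. The exact permutation p of the array offsets, 0.333, decides nothing, since it is the smallest that 2 against 2 arrays allow. Of 100 simulated draws of array offsets 1 gave as large a shift, but the offset size was itself estimated from pairs of arrays. No biological explanation was tested.

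Ribosomal protein and oxidative phosphorylation genes lay above the median gene with THZ1. Random lists matched on signal reached the same height for ribosomal proteins (list median 0.28 against 0.27, a difference of 0.0154). Signal level is therefore one candidate explanation for that list, not shown to be its cause. Oxidative phosphorylation genes lay 0.10 above matched lists, and ribosomal proteins with siMITF 0.30 above, which signal level alone does not account for. No biological explanation was tested.

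Cell division and MITF-linked lists lay below the median gene with siMITF. Signal level was excluded as the whole cause for each: the list medians lay -0.55 (G2/M), -0.49 (G1/S), -0.27 (pigmentation) and -0.18 (MITF targets) from those of matched random lists. The matched lists themselves lay at -0.17, -0.14, -0.12 and -0.17, against list medians of -0.72, -0.64, -0.39 and -0.35. Signal level can therefore match part of each fall. The siRNA groups give no arrays that separate a direct effect of MITF from slower growth, so no biological explanation was tested.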

How the results depend on the processing

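The relative scale (the second centring tried), each gene's own variance and the crossed block were chosen only after the results were seen. Array offsets and 2 arrays per group limit the per-cell results, and the cause was not tested where none is given. Quantile normalization, centring on gene probe sets (median centring) and the relative scale remove by construction a shift of all genes. Genes changed with THZ1 numbered 1208 in the report's test, 4254 with quantile normalization and 4528 with median centring. They numbered 4632 on the relative scale and 0 with each gene's own variance. With siMITF the numbers were 7607, 4546 with quantile normalization and 0 with own variance. Of the 4546, 1872 were lower and 2674 higher, so the larger count turned, and 587 genes lower in the report's test were higher. Tested alone, 1984 probe sets changed with THZ1 and 17778 with siMITF. These are probe sets rather than genes, out of a larger number tested, so they show no change from 1208 and 7607. Numbers changed at least 2-fold with THZ1 were 393, against 153 (quantile), 178 (median), 192 (relative), 177 (mean of probe sets) and 158 (pseudocount 64). With siMITF they were 1635 (1624 lower and 11 higher), against 127 (12 and 115), 132 (77 and 55), 121 (42 and 79) and, at pseudocount 64, 811 (806 and 5). The larger count thus turned with quantile normalization and on the relative scale. The median log2 change with siMITF was -0.63, against 0.0137 (quantile), -0.11 (median) and 0.0014 (relative). Genes with different changes numbered 1288, against 4589 (quantile), 5180 (median), 4965 (relative), 2008 (ERCC centring), 1936 (pseudocount 64) and 276 (trended and robust prior). Of the 1288, 113 were negative and 1175 positive, which turned to 2913 and 1676 with quantile normalization. Genes changed between siCtrl and DMSO numbered 747, against 3302, 2826, 3040, 8469, 388 (trended and robust prior) and 1376 (4 arrays). Genes falling in both numbered 765, against 444 with the trended and robust prior. Lists passing camera fell from 8 to 0 in each comparison with an estimated correlation. Per cell those correlations were 0.77 to 0.97, because the array offset is shared by most genes, so this loss says little about single lists. Lists passing fry rose from 0 to 14 (quantile), 13 (median) and 17 (relative) with THZ1, and to 19, 12 and 17 with siMITF.

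Some changes with siMITF reversed in sign. With quantile normalization CDK7 had 0.27, RPL7 0.14, CDKN1A 0.76, TYR 0.32 and TBX2 0.65. With median centring RPL7 had 0.0361, CDKN1A 0.49, TYR 0.33 and TBX2 0.37. On the relative scale CDK7 had 0.0256, RPL4 0.0229, RPL7 0.0660, CDKN1A 0.53, TYR 0.36 and TBX2 0.44. All 3 settings remove a shift of all genes by construction. Quantile normalization moved some of these genes by more than that shift, and the cause was not tested. Of 1299 values of named genes under siMITF, 1256 kept their call, 22 lost it and 6 gained it. With THZ1, 1087 of 1218 kept it, 90 lost it and 41 gained it. For lists, 463 of 501 values with siMITF and 472 of 501 with THZ1 kept their call.

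Leaving out each array in turn, with the lone array assumed to vary like the others, gave 250 to 2102 genes with THZ1, 1771 to 8551 with siMITF, 82 to 3923 with different changes, 133 to 1345 between siCtrl and DMSO, and 144 to 1536 falling in both. Genes changed at least 2-fold ranged from 216 to 830 with THZ1 and from 781 to 3191 with siMITF. The median change ranged from -0.37 to 0.04 with THZ1 and from -0.77 to -0.49 with siMITF. Lists passing camera ranged from 7 to 10 and from 6 to 8, and lists passing fry from 0 to 0. With the replicate number as a block the counts were 1273 with THZ1, 7787 with siMITF, 1453 with different changes, 816 between siCtrl and DMSO and 821 falling in both, all within 1.5 times the unblocked counts. The numbers share no origin in the labels, and replicate differences correlated at r = 0.11 (DMSO and THZ1) and -0.18 (siCtrl and siMITF), so they were not used as pairs. The crossed block gave 11068 with siMITF.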

Other observations

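The tests in this part were chosen after the gene changes were seen, and their predictions were written before their own values were seen. The histone and p53 target genes named here were chosen after their values were seen. Relative to the median gene, histone genes split with siMITF: H2BC5 had a log2 change of 1.82 and H2AC6 1.07, while H2AX had -0.70 and H2AZ1 -0.32 (n = 2 per group). Of 12 histone genes 6 were higher and 4 lower, and the list gave a camera adjusted p of 0.158. Among 24 p53 targets 11 were higher and 2 lower relative to the median gene, with a camera adjusted p of 0.0393 and of 0.215 with an estimated correlation. SESN2 had 1.003 and CDKN1A, the cell cycle inhibitor p21, 0.53, against per-cell changes of 0.37 and -0.11 that did not pass (adjusted p = 0.160 and 0.682).

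Because ZNF518B was among the largest THZ1 falls, it was asked whether genes named ZNF, mostly zinc finger transcription factors, fell as a family. Of 288 tested, 137 were lower and 9 higher relative to the median gene, that is 47.6% lower against 20.4% of other genes. The family median was -0.25 against 0.04 for random lists matched on signal, a difference of -0.29 that fits the hypothesis. The unadjusted camera p was 1.9e-11, and 0.0378 with an estimated correlation. ZNF518B, which prompted the question, is among the 288 genes. It had -1.75 on the tested probe set and -0.46 on another, relative to the median gene. With siMITF 121 of the family were lower and 0 higher per cell, and 28 lower and 84 higher relative to the median gene (unadjusted camera p = 0.000133, 0.157 with an estimated correlation). Whether short-lived mRNAs account for the fall was not tested.

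It was asked whether genes that fell at least 2-fold with siMITF relative to the median gene also lay lower with THZ1. MITF, which fell 1.65-fold on that scale, was not among them. The 42 genes had a median relative change with THZ1 of -0.10, against 0.04 for matched lists (-0.08 to 0.14). The difference of -0.14 fits the hypothesis as far as the choice of genes goes. The interval holds no spread between arrays, and no test across arrays was run for these 42 genes. Of these genes 15 were lower and 6 higher with THZ1 relative to the median gene, against 21.1% lower and 17.7% higher of all tested genes.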
